A study of Mus musculus with 2 samples.

How the data were processed

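Single-cell RNA was measured with 10x Genomics droplets in 2 libraries, 1 of unstimulated cells and 1 of cells given recombinant mouse IL-23, both groups as the labels name them. Per the labels' protocols, the small intestine of Il23r-eGFP mice was freed of Peyer's patches, epithelium was removed with EDTA, the remaining tissue was digested with collagenase, leukocytes were enriched on a Percoll gradient and live eGFP-positive cells were sorted. The labels do not say how many animals gave the cells, nor whether the unstimulated cells were incubated for as long as the stimulated ones. The protocol text of both samples mentions the stimulation with IL-23, so which cells went without it rests on the group labels alone.

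The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, for 32285 genes. Per the submitters' processing notes, the genome build was mm10 and the tool was Cell Ranger 3.1.0, while per the file headers of the matrices it was cellranger 6.0.0. Both versions are given because nothing in the sources settles which made these counts. The annotation and the rule that separated cells from empty droplets are not given in the sources used here. Symbols and gene identifiers were taken from the deposited feature tables. Positions on GRCm38 came from a GENCODE annotation of that build, matched by gene identifier. No symbol of the reporter itself was used here.

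Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs. Scrublet, run in each library with an expected doublet share of 8%, called 0% and 0.0108% of the cells, so this doublet call did not work and doublets remain among the kept cells. Kept cells numbered 20040 of 21536 barcodes. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries. Genes of the lists that IL-23 was thought to move, cell cycle, mitochondrial and ribosomal genes and antigen receptor V segments were left out of the clustering, so that clusters would follow identity more than the stimulus. Genes were scaled within each library, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used (Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, igraph 0.11.9, seed 7).

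Clusters were named from 19 marker lists for ILC3s, their subsets, T cells and the other cell types that the tissue could hold. A cluster took a name from at least 3 markers detected in 25% of its cells. For ILC3-like this did not separate clusters, because the T-like, macrophage-like and unnamed clusters also held at least 3 ILC3 markers. ILC3-like was thus the default name of clusters that neither another class nor few UMIs set aside. Its top 10 genes were ranked by fold, with 10 CPM added, among genes detected in 25% of its cells. A cluster whose top 10 was led by markers of another class took that class's name when at least 3 of that class's markers were detected. Otherwise it stayed unnamed, as did a cluster led by cycling markers. A cluster also stayed unnamed when its median UMIs were under the library's median divided by 3 with no ILC3 marker in that top 10. ILC3-like clusters were placed in the NCR+ or CCR6+ subset when the markers of 1 subset above the pool of ILC3-like cells outnumbered those of the other by at least 4, and were otherwise called other ILC3-like. This naming rule and the subset threshold were set after the clusters had been seen. The T-like class joins the gamma delta and alpha beta T-like clusters.

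UMIs were summed per library and class and scaled to the class total to give CPM, the usual relative abundance of a transcript. Each ratio was the log2 of the stimulated over the unstimulated CPM with 0.5 UMI added to each sum, except that ratios within single clusters are plain quotients of CPM. Genes counted as measured with at least 10 CPM in 1 or both libraries and at least 20 UMIs over both. Sums carry exact Poisson 95% intervals and shares of cells exact binomial (Clopper-Pearson) 95% intervals (scipy 1.17.1). All these intervals cover counting error alone. With 1 library per group there is no test of any difference and no replicate check, so no p-value was computed, and sizes of at least 1.5-fold were counted as sizes.

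For each of 21 gene lists, the median log2 ratio of its measured members was given with a 95% interval from 1000 Poisson resamples. Its percentile among 10000 random lists of the same size, drawn from the 100 genes nearest in mean expression to each member, is a description of these 2 libraries. The lists were effector cytokines of type 17 cells and ILC3s, STAT3 targets, checkpoint receptors, co-stimulatory receptors and ligands, MHC class II, lineage transcription factors, cytokine and chemokine receptors, NF-kB targets, immediate early genes, heat shock genes, glycolysis and hypoxia, oxidative phosphorylation, ribosome biogenesis, cholesterol synthesis and uptake, the unfolded protein response, the type I interferon response, cell cycle, cytotoxic effectors, chemokines, apoptosis regulators and mitochondrially encoded genes.

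Genes were named by a rule of size. Among genes with at least 50 CPM in 1 or both libraries, at least 30 UMIs and intervals that did not overlap, the 15 highest and 10 lowest ratios were taken in ILC3-like and in T-like cells. The 5 highest and 3 lowest were taken in each smaller class with at least 100 cells per library. Mitochondrial and ribosomal protein genes, gene models without a symbol of their own and antigen receptor segments were left out. Members of the lists, the markers and Il23r could also be named. Some genes that the rule takes are not reported here. Filters, lists, markers, the naming rule for genes and most alternatives were chosen before the data were examined.

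Shares of cells with a UMI of a gene were given as counted and after each cell was thinned to 3370 UMIs, the 10th percentile over kept cells, with shallower cells left out. Macrophage-like cells, the class that should lack Il23r and Ctla4, give the background for such shares.

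Gene ratios, Poisson intervals and list percentiles, but not filtering or clustering, were tested on simulated data drawn from the real class totals. In ILC3-like cells (6827 genes), 100% of genes altered 2-fold and 100% of those altered 4-fold came out in the right direction at 1.5-fold or more, with median absolute log2 errors of 0.023 and 0.031, and 0% of unaltered genes reached 1.5-fold. In T-like cells (7348 genes) these shares were 99.0% for 2-fold and 100% for 4-fold, with errors of 0.11 and 0.10, and 1.68% of unaltered genes reached 1.5-fold. Poisson intervals held the true mean for 95.3% of genes in ILC3-like and 95.5% in T-like cells. The simulated sums were themselves Poisson draws without spread between cells, so this coverage and the shares above check the calculation alone. They do not cover genes whose UMIs come mostly from single cells. Of 100 unaltered lists, 12% lay under the 5th or over the 95th percentile in each class, near the share that these bounds set by themselves. Percentiles near these bounds thus arise without any alteration and carry little alone.

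Alternatives varied the cell filters, the doublet step, the clustering, the class definition, the scaling (including TMM factors from edgeR 4.0.16 in R 4.3.3), thinning, the weight of cells, the pseudocount and the filter on low genes. A further 4 alternatives were chosen after seeing the data. They left out the 8% of cells with the highest Scrublet scores, classed cells by CD3 chain transcripts alone, left out the ILC3-like cluster with the most UMIs per cell, and left out the cell with the most UMIs of each gene. Figures were drawn with matplotlib 3.10.9.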

Results

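Single-cell transcriptomes were collected from IL-23 receptor reporter cells of the small intestine of healthy mice, in which green fluorescence marks cells that express the receptor of the cytokine IL-23. The 2 libraries, 1 unstimulated and 1 exposed to IL-23 over 2 hours, address which cells of the gut carry this receptor and how each responds to its ligand. The unstimulated library held 11096 barcodes with 58443284 UMIs (median 4877 per barcode), and the stimulated library held 10440 barcodes with 62291905 UMIs (median 5804.5). After filtering, 10790 unstimulated cells (58148889 UMIs, median 4928 UMIs and 1862.5 genes per cell) and 9250 stimulated cells (61346987 UMIs, median 6086.5 UMIs and 2056 genes) remained. Each group was 1 library, so no difference below was tested or has a replicate check, and every value is a sum of UMIs in CPM or a share of cells with a 95% interval that covers counting error only.

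Nearly all sorted cells resembled group 3 innate lymphoid cells (ILC3s), the receptor-bearing lymphocytes that make IL-22 at the gut barrier. ILC3-like cells made up 92.8% (95% interval 92.3 to 93.3) of unstimulated and 92.6% (92.1 to 93.1) of stimulated cells. These shares were set in part by the eGFP sort and by a naming rule in which ILC3-like was the default. T-like cells made up 5.73% (5.30 to 6.18, 618 cells) and 5.22% (4.78 to 5.69, 483 cells). Of all cells, gamma delta T-like cells were 3.94% (3.58 to 4.32) and 3.63% (3.26 to 4.03), and alpha beta T-like cells were 1.79% (1.55 to 2.06) and 1.59% (1.34 to 1.87). The macrophage-like cluster held 14 and 7 cells. A further 3 unnamed clusters held 1.33% (1.13 to 1.57) of unstimulated and 2.09% (1.80 to 2.40) of stimulated cells. They were led by the B-cell genes Ebf1 and Cd79b (cluster 10, 65 and 48 cells), by nuclear long noncoding RNAs at a median of 1169 and 1606.5 UMIs (65 and 122 cells), and by the cycling genes Top2a and Mki67 (14 and 23 cells). Cluster 10 also held the plasma cell transcripts Igkc (49475 and 16080 UMIs) and Jchain (18900 and 8710 CPM), while Igkc lay between 2.99 and 22.5 CPM in every ILC3-like cluster. When cells were instead classed by their own transcripts without clusters, the ILC3-like share was 28.3% and 28.8% and the T-like share 66.1% and 65.8%. That definition places ILC3-like cells with any T cell receptor transcript among T-like cells. A UMI of the CD3 chain gene Cd3e was found in only 0.160% of unstimulated and 0.280% of stimulated ILC3-like cells of the clusters. Shares by CD3 chain transcripts alone are given below.

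The ILC3-like cells fell into a subset with markers of NCR+ ILC3s, a subset with markers of CCR6+ ILC3s (the lymphoid tissue inducer-like kind), and a remainder. NCR+ cells were 34.2% (33.3 to 35.1) and 35.3% (34.3 to 36.3) of the unstimulated and stimulated cells, CCR6+ cells 24.9% (24.0 to 25.7) and 24.95% (24.1 to 25.8), and other ILC3-like cells 33.7% (32.8 to 34.6) and 32.3% (31.4 to 33.3). Among NCR+ cells, cluster 5 held 19.0% and 15.1% of all cells and cluster 6 held 9.95% and 14.9%. These shares and the subset of a cluster depend on the clustering. With barcodes of at least 200 genes kept, the cluster that shared 4 of the 10 leading genes of cluster 6 held 9.86% and 9.68% and was placed among the other ILC3-like cells. The 10 leading genes of NCR+ cluster 0 began with Cwc25 and Arl5c and included Dusp4, Nfkbid, Tbx21, Cxcl2 and Zfp36. Those of CCR6+ cluster 1 included heat shock and immediate early genes (Hspa1a, Hsph1, Egr1, Fos, Fosb).

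Transcripts of the IL-23 receptor were present in both lymphocyte classes and stood higher in the stimulated library. In ILC3-like cells Il23r (ENSMUSG00000049093, GRCm38 chromosome 6, 67422932 to 67491855) was at 129 CPM (126 to 133) unstimulated and 187 CPM (184 to 191) stimulated. In T-like cells it was at 136 CPM (125 to 147) and 216 CPM (202 to 232), with gamma delta T-like cells at 160.5 and 254 CPM and alpha beta T-like cells at 84.6 and 137 CPM. An Il23r UMI was found in 43.9% of unstimulated and 61.2% of stimulated ILC3-like cells (median 4887.5 and 6064 UMIs per cell) and in 52.4% and 71.6% of T-like cells (6145.5 and 7231 UMIs). After thinning to equal depth these shares were 33.2% (32.2 to 34.1) and 42.5% (41.4 to 43.6) in ILC3-like cells, leaving out 1165 and 547 cells, and 34.7% (30.8 to 38.7) and 47.3% (42.6 to 52.0) in T-like cells, leaving out 44 and 28. Background in macrophage-like cells (6633.5 and 6183 UMIs) was 1 of 14 and 1 of 7 cells. The level lies under 1 UMI per thinned cell, so the comparison between libraries rests on the CPM.

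Stimulated ILC3-like cells held far more RNA of the cytokines Il22, Il17a and Il17f, while the effector cytokines as a list went both ways. Il22, which drives epithelial defence, was at 5883 CPM (5862 to 5903) unstimulated and 26673 CPM (26630 to 26715) stimulated, 4.53-fold higher and equal to 2.67% of all their UMIs against 0.588%. Il17a and Il17f, the neutrophil-recruiting cytokines of type 17 cells, were 11.99-fold (25.4, 24.1 to 26.8, against 305, 301 to 309.9) and 7.71-fold (95.9 against 739) higher. Batf, an AP-1 family transcription factor of type 17 cells, had the highest ratio, 17.7-fold, from 30.1 CPM (28.6 to 31.6) to 531 CPM (525 to 537). The inhibitory receptor gene Ctla4 was 12.2-fold higher, at 14.7 CPM (13.7 to 15.7) and 179 CPM (176 to 183).

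The rest of the 15 highest ratios in ILC3-like cells were those of genes of varied kinds, and no common function was tested. The stress sensor Gadd45g was at 121 and 1143 CPM, the transcriptional repressor Prdm1 (Blimp-1) at 12.8 and 86.3 CPM, and the NF-kB cofactor Bcl3 at 20.2 and 106 CPM. Sbno2, a STAT3-induced corepressor, was at 27.9 and 149.9 CPM, and the transcription factor Cebpd at 50.6 and 216 CPM. The IL-1 receptor gene Il1r1 was at 71.8 and 356 CPM, 4.96-fold higher. The fatty acid elongase gene Elovl6 was at 18.2 and 100.1 CPM, the DNA repair gene Apex1 at 16.5 and 73.9 CPM, the membrane protein gene Stom at 59.1 and 274 CPM, and Pqlc1 at 24.2 and 206 CPM. Batf (ENSMUSG00000034266) lies on GRCm38 chromosome 12 at 85686669 to 85709087, Ctla4 (ENSMUSG00000026011) on chromosome 1 at 60887000 to 60915832, Il22 (ENSMUSG00000074695) on chromosome 10 at 118204942 to 118210047, and Il17a (ENSMUSG00000025929) and Il17f (ENSMUSG00000041872) on chromosome 1 at 20730905 to 20734496 and 20777146 to 20790617.

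Among the genes named by the rule, which asks for at least 50 CPM, lower ratios in ILC3-like cells were smaller in size. Clec2d, the ligand of an NK cell receptor, was 2.44-fold lower (71.4 against 29.3 CPM), and the PI3 kinase regulatory subunit gene Pik3r1 was 2.06-fold lower (433 against 211 CPM). The survival gene Bcl2 was at 107 and 52.7 CPM, and the translation inhibitor Pdcd4 at 357 and 178 CPM. Stap1 (90.5 and 39.1 CPM), Coq8a (55.4 and 23.3), Ccrl2 (94.0 and 45.3), N4bp2l1 (52.3 and 24.4) and Bicd1 (122 and 60.9) were between 2.00-fold and 2.38-fold lower. Bcl2a1b was at 70.1 and 35.0 CPM, a value that stays uncertain because its reads can be split with near-identical copies such as Bcl2a1d.

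**Figure D1:**
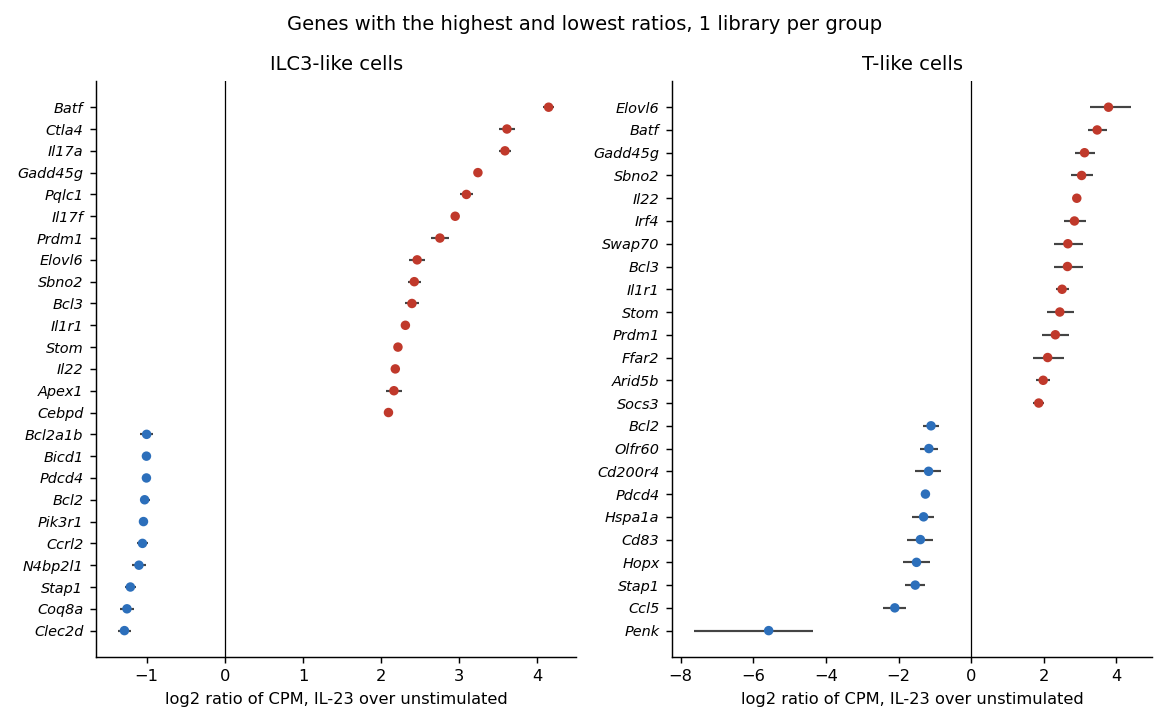
Log2 ratio of CPM, stimulated over unstimulated, for genes with the highest (red) and lowest (blue) ratios in ILC3-like cells (left) and T-like cells (right), 1 library per group, with lines for intervals from Poisson counting error. Ratios reach 4.14 for Batf in ILC3-like cells and 3.78 for Elovl6 in T-like cells, and Penk in T-like cells, at -5.58, rests on 1 cell.

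The fixed gene lists place these genes in groups. STAT3 targets, the genes of the factor that the IL-23 receptor activates, stood higher in ILC3-like cells. Of 18 measured, 8 were at least 1.5-fold higher, 1 lower and 9 between, with a median log2 ratio of 0.51 (0.49 to 0.53) above all matched random lists (percentile 100, matched median -0.054). Socs3, a feedback inhibitor of cytokine signalling, was at 257 and 809 CPM, Myc at 4.94 and 25.7, the aryl hydrocarbon receptor gene Ahr at 43.1 and 139 and the kinase gene Pim2 at 81.2 and 219, while Socs2 was lower (148 and 98.3). Effector cytokines went both ways. Of 12 measured, 5 were higher (Il17a, Il17f, Ifng, Il22, Tnfsf14), 2 lower (Ltb, 98.9 and 53.6 CPM, and Tnf, 39.1 and 25.7) and 5 between, with a median of 0.078 (0.030 to 0.13) at percentile 99.3 (matched median -0.092).

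Checkpoint receptors showed opposite signs of median and mean. Of 8 measured in ILC3-like cells, 2 were higher (Ctla4, and Cd244a at 4.97 and 27.3 CPM), 3 lower (Nt5e at 57.2 and 33.4, Cd160 at 11.9 and 7.12, Cd200r1 at 23.6 and 15.6) and 3 between, among them Pdcd1 (81.7 and 56.8). The median was -0.30 (-0.36 to -0.24, percentile 1.84, matched median -0.12) and the mean 0.44. Co-stimulatory genes had 2 of 7 higher (Icos, 515 and 1047 CPM, and Tnfrsf18, which encodes GITR, 244 and 454), 2 lower (Cd27, 20.2 and 10.8, and Cd83) and 3 between, at percentile 62.7 with a median of -0.041 and a mean of 0.040. With cells classed by their own transcripts, the effector cytokine median was -0.068 and the checkpoint median 0.0092, both of the opposite sign. Among effector cytokines with at least 50 CPM the median was 1.21.

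Genes of identity and of cytokine sensing shifted in part. Lineage transcription factors had 5 of 20 higher (among them Ahr, Zeb2 and Ikzf1), 2 lower (Gata3, the type 2 regulator, 57.9 and 33.5 CPM, and Maf, 265 and 176) and 13 between, with a median of 0.18 (0.12 to 0.22) at percentile 100. Cytokine and chemokine receptors had 6 of 21 higher, among them Il1r1, Il6st (7.63 and 18.1 CPM) and the egress receptor S1pr1 (13.7 and 25.1). Another 3 were lower (Cxcr4, 26.1 and 9.74, Cxcr6, 648 and 361, and Kit, 511 and 316) and 12 between, with a median of -0.024 (percentile 92.1) and a mean of 0.16. Cytotoxic effector genes had 2 of 11 higher (Gzma and Gzmb, 28.1 and 49.2 CPM), 0 lower and 9 between, with a median of 0.15 at percentile 99.9. MHC class II genes had 6 of 6 between, with a median of 0.032 (percentile 92.4) and a mean of -0.014. Chemokines had 0 of 7 higher, 1 lower (Cxcl10) and 6 between, with a median of -0.18 at percentile 27.7.

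Metabolic and stress groups in ILC3-like cells were mostly within 1.5-fold. Glycolysis and hypoxia genes had 4 of 21 higher (Ndrg1, Hk1, Ldha at 194 and 351 CPM, Ero1l), 1 lower (Hk2, 658 and 343) and 16 between, with a median of 0.066 at percentile 99.95. Cholesterol genes had 1 of 13 higher (Fdft1), 2 lower (Sqle, 39.8 and 21.1 CPM, and Idi1, 279 and 181) and 10 between, with a median of -0.35 (-0.40 to -0.29) at percentile 0.16. Heat shock genes had 11 of 11 between, with a median of -0.24 at percentile 1.17. The unfolded protein response had 0 of 18 higher, 1 lower (Pdia4) and 17 between (median -0.12, percentile 10.5). Oxidative phosphorylation had 20 of 20 between (median -0.060, percentile 50.02) and ribosome biogenesis 18 of 18 between (median -0.059, percentile 58.8). Mitochondrially encoded genes, a sign of RNA quality, had 12 of 13 between and mt-Atp8 lower, with a median of 0.24 (percentile 99.98), and mitochondrial UMIs were 2.62% of the unstimulated and 3.21% of the stimulated total.

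Signalling groups other than STAT3 split within ILC3-like cells. Immediate early genes had 2 of 18 higher (Jund, 388 and 936 CPM, and the mRNA decay factor Zfp36), 4 lower (Nr4a1, 386 and 230.2, Nr4a3, Klf4, Dusp5) and 12 between, with a median of 0.042 at percentile 97.7. NF-kB targets had 1 of 18 higher (the adhesion molecule gene Icam1, 211 and 354 CPM), 3 lower (Tnfaip3, 389.6 and 236, Bcl2a1b, Bcl2a1d) and 14 between, with a median of -0.079 at percentile 47.4. Interferon response genes had 3 of 13 higher (Gbp2, 25.2 and 65.8 CPM, Ifi203, Stat2) and 10 between (median -0.083, mean 0.16, percentile 61.2). Apoptosis regulators had 2 of 16 higher (the death receptor gene Fas, 12.2 and 37.6 CPM, and Casp8), 2 lower (Bcl2 and Bbc3) and 12 between (median -0.0091, mean 0.021, percentile 97.2). Cell cycle genes had 1 of 6 higher (Mcm3) and 5 between (median -0.29, percentile 3.13). The median ratio of all 6964 measured genes was -0.11, and TMM scaling raised it by 0.12 (by 0.079 in T-like cells). Negative list medians within those sizes thus have no direction of their own, and small medians of either sign are read against matched lists.

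**Figure D2:**
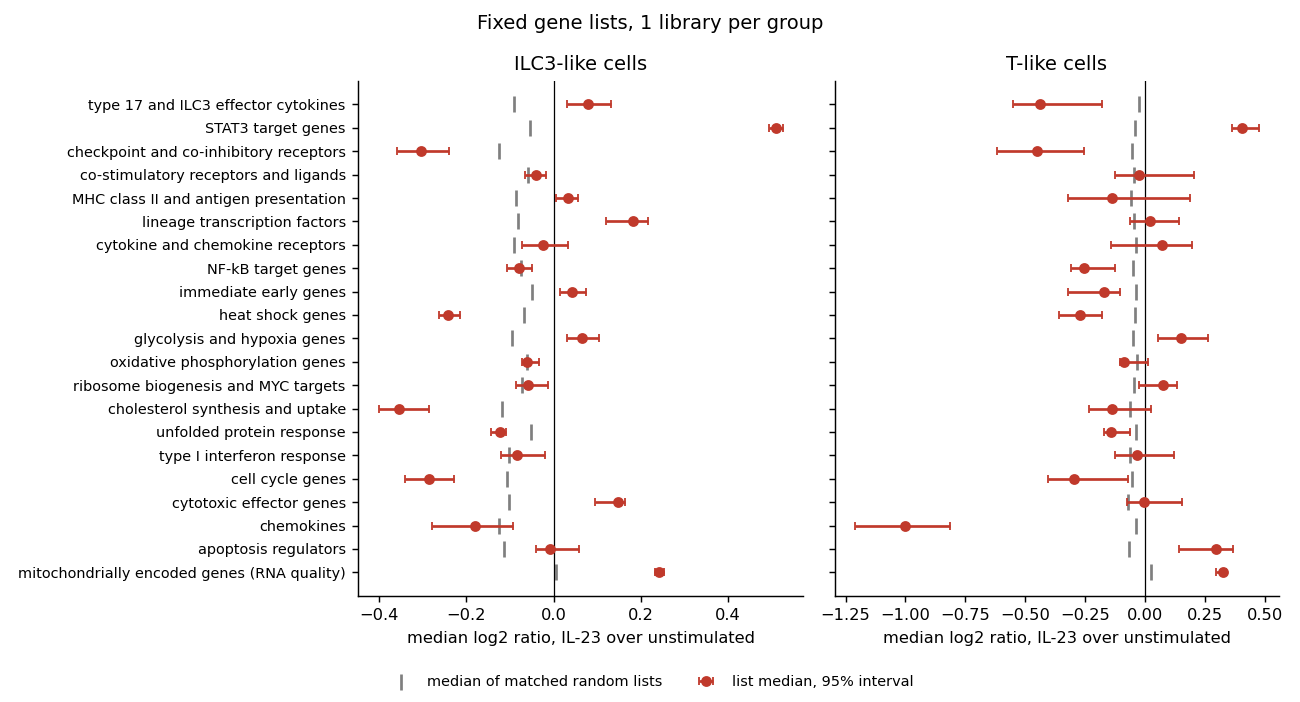
Median log2 ratio, stimulated over unstimulated, of each fixed gene list in ILC3-like cells (left) and T-like cells (right), red points with 95% intervals from Poisson resampling, 1 library per group, and gray ticks for the median of matched random lists. STAT3 targets lie at 0.51 and 0.40, and chemokines in T-like cells at -1.0.

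Taken as a whole, the NCR+ subset had a lower baseline and larger ratios than the CCR6+ subset for Il22, Batf, Il17a and Gadd45g, a difference that was not tested and did not hold for every cluster. Il22 was at 3226 and 28734 CPM in NCR+ cells (8.91-fold) and at 7664 and 23166 CPM in CCR6+ cells (3.02-fold). Batf was 27.2-fold (21.4 and 583 CPM) and 9.40-fold (49.9 and 470.0) higher, Il17a 23.7-fold (9.11 and 216) and 9.17-fold (29.5 and 271), and Gadd45g 13.9-fold (97.7 and 1357) and 5.96-fold (155 and 924). The other ILC3-like cells were not summed apart. Stimulated Il17a was at 305 CPM in all ILC3-like cells, above both subsets, so it stood higher in those other cells than in either subset. In NCR+ cluster 0, Il17a was only 4.19-fold and Il17f 4.13-fold higher, against 22.8-fold and 15.9-fold in CCR6+ cluster 8, and unstimulated Il22 was at 8052 CPM, against 4968 in cluster 8. The Il17a ratio was 58.5-fold in NCR+ cluster 6 and 15.4-fold in NCR+ cluster 5. Il17f in NCR+ cells was at 27.4 and 485 CPM, and in CCR6+ cells Sbno2 was at 27.1 and 187 CPM and Pqlc1 at 24.6 and 166. The highest ratio in NCR+ cells was that of granzyme A (Gzma), 33.4-fold (1.65 CPM, 1.16 to 2.28, against 55.9, 52.9 to 58.9), from 21 and 223 cells with a UMI. Among the lowest were Stap1 (86.3 and 25.2 CPM), Bcl2 (72.3 and 22.8) and Coq8a (63.9 and 20.9) in NCR+ cells, and Clec2d (93.3 and 37.7) and Nfe2l1 (173 and 94.3) in CCR6+ cells.

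Ctla4 RNA in ILC3-like cells lay mainly, but not only, in the NCR+ subset. Of the 2157 stimulated ILC3-like cells with a Ctla4 UMI, 1611 were NCR+ and 138 CCR6+, and the rest were other ILC3-like cells. In NCR+ and CCR6+ cells its levels were as follows. It was at 29.5 CPM (27.3 to 31.8) and 362 CPM (354 to 369.5) in NCR+ cells and at 2.18 (1.47 to 3.11) and 14.7 (12.9 to 16.8) in CCR6+ cells. Among T-like cells it was at 179 and 834 CPM in gamma delta and at 1085 (1030.5 to 1142) and 1226 (1166 to 1289) in alpha beta T-like cells. A Ctla4 UMI was found in 10.6% of unstimulated and 49.3% of stimulated NCR+ cells (median 5718 and 7075 UMIs), and after thinning in 7.26% (6.43 to 8.16) and 38.8% (37.1 to 40.6), leaving out 97 and 106 cells. In CCR6+ cells (4699 and 5786 UMIs) the shares were 0.969% and 5.98%, thinned 0.611% and 3.71% with 227 and 96 cells left out, and among macrophage-like cells it was 1 of 14 and 1 of 7 cells. The 1 unstimulated cell held all 15 Ctla4 UMIs (119 CPM) of a cluster that also held 15 UMIs of Trdc, so this background is loose. As counted, the CCR6+ shares do not exceed it, but 14 and 7 cells are too few for this to decide anything. After thinning, the macrophage-like background was 1 of 12 unstimulated and 0 of 7 stimulated cells. Unstimulated NCR+ cells can only be set against the CCR6+ cells of the same library.

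**Figure D3:**
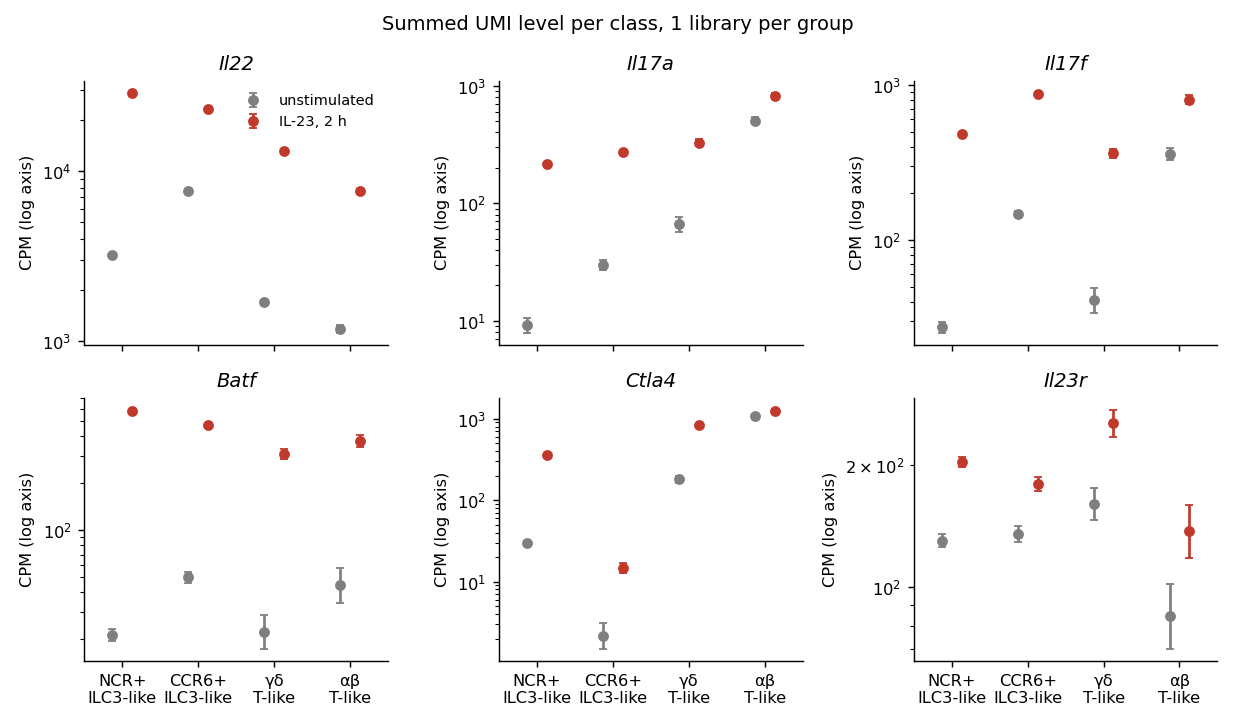
CPM on log axes of 6 genes in 4 cell classes, unstimulated in gray and stimulated in red, 1 library per group, with exact Poisson 95% intervals as bars. Il22 in NCR+ ILC3-like cells lies at 3226 and 28734 CPM, and Ctla4 in alpha beta T-like cells at 1085 and 1226.

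T-like cells of the stimulated library also held more RNA of Il22, Il17a and Il17f and of the transcription factor genes Batf and Irf4. Il22 was 7.50-fold higher, at 1517 CPM (1480.3 to 1555) and 11382 CPM (11276 to 11488), against 269 (186 to 376) and 2029 (1690.4 to 2416) in macrophage-like cells, which should lack it. Elovl6 had the highest ratio, 13.7-fold (7.18 CPM, 4.85 to 10.3, and 100.2, 90.5 to 111), followed by Batf, 11.1-fold (29.7, 24.7 to 35.4, and 329.7, 312 to 348). This order depends on the setting: with cells classed by their own transcripts the log2 ratio was 2.64 for Elovl6 and 4.16 for Batf, and with 10 CPM added it was 2.68 and 3.097 (3.78 and 3.47 otherwise). Il17a and Il17f were at 210.0 and 484 CPM and at 145 and 504 CPM. The type 17 regulator Irf4 was 7.17-fold higher (24.9 and 179 CPM).

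Other high ratios in T-like cells were those of Gadd45g (28.7 and 251 CPM), Sbno2 (25.9 and 214), Swap70 (14.6 and 93.0), Bcl3 (15.1 and 95.3), Il1r1 (74.2 and 421), Stom (17.7 and 96.6) and Prdm1 (17.96 and 89.9). The short-chain fatty acid receptor gene Ffar2 was at 14.6 and 63.2 CPM, Arid5b at 67.8 and 268 and Socs3 at 117 and 424. Lower in T-like cells were Stap1 (103 and 35.5 CPM), Cd83 (59.9 and 22.6), Pdcd4 (428 and 179), Cd200r4 (52.9 and 23.4), Olfr60 (107 and 47.5) and Bcl2 (147 and 68.1). Hspa1a (83.1 and 33.4 CPM) shares reads with Hspa1b and stays uncertain, and it was found in only 5.99% of unstimulated and 5.59% of stimulated cells. Single unstimulated cells carried other low ratios. In the enkephalin gene Penk (55.1 and 1.03 CPM) 1 cell held 223 of 230 UMIs, in Ccl5 (114 and 26.5) 279 of 477, and in Hopx (60.1 and 21.1) 72 of 251. Without the top cell of each library, the log2 ratio was -1.48 for Penk (-5.58 with it), -4.14 for Ccl5 (-2.10) and -1.27 for Hopx (-1.51).

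By list, STAT3 targets in T-like cells had 9 of 20 higher (among them Batf, Irf4, Myc at 12.9 and 46.5 CPM, and Pim2 at 56.3 and 143), 0 lower and 11 between, with a median of 0.40 (0.36 to 0.48) at percentile 100. Effector cytokines had 3 of 10 higher (Il22, Il17f, Il17a), 4 lower (Ltb, 299 and 139 CPM, Tnfsf11, 173 and 107, Lta, and Areg, where 1 cell held 440 of 928 unstimulated UMIs) and 3 between. Their median was -0.44 (-0.55 to -0.18, percentile 0), or -0.26 without the top cell of each gene, and their mean 0.21. By subset the median was -0.15 (-0.28 to -0.0068, percentile 16.7) in gamma delta and 0.26 (-0.30 to 0.59, percentile 99.0) in alpha beta T-like cells. Checkpoint receptors had 1 of 9 higher (Ctla4, 477 and 961 CPM), 4 lower (Pdcd1, 156 and 94.1, Cd160, Havcr2, Cd200r1) and 4 between, with a median of -0.45 (-0.62 to -0.25) at percentile 0.1. The checkpoint median was -0.48 (-0.67 to -0.25, percentile 0.2) in gamma delta cells, with Ctla4 higher. In alpha beta cells it was -0.27 (-0.46 to 0.012, percentile 5.82), with Lag3 higher and Btla, Tigit and Lgals9 lower. Chemokines had 1 of 6 higher (Cxcl9) and 5 lower, with a median of -1.0 (-1.21 to -0.81, percentile 0). Cxcl10 went opposite ways: gamma delta cells had 3 of 5 chemokines lower, Cxcl10 among them (median -0.84), and alpha beta cells 2 of 6 higher (Cxcl9, Cxcl10) and 4 lower (median -1.93). Few cells carried these chemokines: 1 unstimulated cell held 150 of the 381 UMIs of Cxcl3 and 1 held 140 of the 311 of Cxcl10. Apoptosis regulators had 3 of 16 higher (Fas, 16.5 and 46.5 CPM, Pmaip1, Bcl2l11), 2 lower (Bcl2, Bbc3) and 11 between, with a median of 0.30 (0.14 to 0.37) at percentile 100. Their median was 0.25 (0.12 to 0.44, percentile 99.96) in gamma delta and 0.072 (-0.10 to 0.27, percentile 89.4) in alpha beta cells. Counting every cytokine with a UMI, the effector median in T-like cells was 0.00066, of the opposite sign.

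NF-kB targets and immediate early genes stood lower than matched lists in T-like cells as a whole. Their intervals in gamma delta and alpha beta T-like cells overlap, and no difference between these subsets was tested. NF-kB targets had 1 of 17 higher (Icam1, 83.3 and 159.6 CPM), 1 lower (Tnfaip3, 549.8 and 347) and 15 between, with a median of -0.26 (percentile 0.08), or -0.32 (-0.38 to -0.088, percentile 0.03) in gamma delta and -0.047 (-0.17 to 0.098, percentile 43.2) in alpha beta cells. Immediate early genes had 2 of 19 higher (Jund, Zfp36), 4 lower (Nr4a1, Klf4, Dusp5, Egr1) and 13 between (median -0.17, percentile 1.67), with medians of -0.27 (-0.36 to -0.16, percentile 0.06) in gamma delta and -0.059 (-0.17 to 0.088, percentile 40.2) in alpha beta cells. Heat shock genes had 2 of 11 lower (Hspa1a, Hspa1b) and 9 between (median -0.27, percentile 1.33), and the unfolded protein response 1 of 18 lower and 17 between (median -0.14, percentile 5.55). Cell cycle genes had 1 of 11 higher (Mki67) and 10 between (median -0.30, percentile 1.39). Interferon response genes had 4 of 16 higher (Gbp2, Ifi203, Igtp, Stat2), 3 lower (Irf7, Ifit1, and Rsad2, where 1 cell held 73 of 80 unstimulated UMIs) and 9 between, with a median near that of matched lists (-0.032 against -0.060, percentile 66.7). By subset, the interferon median was -0.0094 (-0.20 to 0.13, percentile 78.4) in gamma delta cells, with 5 of 17 higher and 5 lower, and 0.16 (0.024 to 0.51, percentile 98.8) in alpha beta cells, with 3 of 15 higher (Ifit1, Gbp2, Irf1) and 1 lower. In gamma delta cells 1 unstimulated cell held 81 of the 115 UMIs of Ifit1 and 1 held 39 of the 40 of Oasl1.

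Among the remaining lists in T-like cells, glycolysis and hypoxia had 3 of 22 higher (Ero1l, 123 and 362 CPM, Pfkfb3, Hk1), 2 lower and 17 between (median 0.15, percentile 99.85). Receptors had 4 of 21 higher (Il1r1, Il18rap, Il17re, Il23r), 4 lower (Cxcr4, Ccr9, Kit, Ccr7) and 13 between (median 0.073, percentile 96.9), with medians of 0.29 (0.10 to 0.36, percentile 100) in gamma delta and -0.049 (-0.18 to 0.083, percentile 48.1) in alpha beta cells. Lineage factors had 5 of 20 higher (among them Ahr, Ikzf1 and Nfil3), 1 lower (Lef1) and 14 between (median 0.020, percentile 87.4), and ribosome biogenesis 1 of 18 higher (Rrp1b) and 17 between (median 0.077, percentile 97.9). Co-stimulatory genes had 1 of 11 higher (Tnfrsf4, 69.9 and 129.8 CPM), 2 lower and 8 between (median -0.026, percentile 61.6). Cholesterol genes had 1 of 13 higher and 12 between (median -0.14, percentile 18.9). Between 1.5-fold bounds lay 5 of 5 MHC class II genes (median -0.14, mean 0.031, percentile 26.2), 20 of 20 oxidative phosphorylation genes (median -0.089, percentile 17.4) and 10 of 10 cytotoxic genes (median -0.0044, mean 0.11, percentile 77.3). By subset, 3 of 10 cytotoxic genes were higher in gamma delta cells (Gzma, Prf1 and Gzmb, median 0.073, mean 0.58) and 2 of 11 lower in alpha beta cells (Klrd1 and Fasl, median -0.11), a contrast that was not tested. Mitochondrially encoded genes had a median of 0.33 (percentile 100), with mitochondrial UMIs at 2.87% and 3.65%.

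Gamma delta and alpha beta T-like cells differed in where they started. In gamma delta cells Il17a was at 66.3 and 327 CPM (4.92-fold), Il17f at 41.0 and 361 and Il22 at 1685 and 13162. In alpha beta cells Il17a was at 504 and 813 CPM (1.61-fold), Il17f at 359 and 803 and Il22 at 1174 and 7663 (6.53-fold). The highest ratios in gamma delta cells were those of Gzma (3.21 and 66.9 CPM, in 2 and 24 cells), Elovl6 (6.06 and 85.1), Irf4 (10.7 and 148), Batf (22.5 and 308) and Sbno2 (24.6 and 229), and in alpha beta cells those of Gadd45g (14.6 and 219), Elovl6 (9.48 and 132), Batf (44.5 and 376), Il22 and Sbno2 (28.4 and 182). Lowest in gamma delta cells were Ccl5 (51.0 and 3.42 CPM, with 70 of 143 UMIs from 1 of 6 cells), Hspa1a (93.4 and 23.9) and Stap1 (81.3 and 21.3). Hspa1a was found in only 5.88% of unstimulated and 4.17% of stimulated gamma delta cells. In alpha beta cells Penk (168 and 3.18 CPM, with 223 of 230 UMIs) and Areg (396 and 72.2, with 440 of 543) each rested mostly on 1 unstimulated cell, and Ccl20 (148 and 23.0) came from 25 and 8 cells.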

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

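The tests of Ctla4 and of barcodes with few genes were chosen after those results were seen, those of Il22 before except that of clustered ILC3s by their abundant transcripts, and the rule for lists moving opposite ways was loosened from 1.5-fold to intervals that exclude 0 after the stricter form gave none.

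List medians that lay above 0 in one class and below 0 in the other, each with its interval excluding 0, drew attention in 4 cases, and in each the difference was not tested. All 21 lists were screened in 3 pairs: NCR+ with CCR6+, ILC3-like with T-like, and gamma delta with alpha beta T-like cells. The last pair gave no such list, and no gene named by the rule of size went opposite ways in any pair. Medians of about 0.12 or less in size lie within the shift that scaling alone brought in ILC3-like cells, which was upward. The sign of small negative medians against 0 thus carries little by itself, while small positive ones would move further from 0. Small medians of either sign are read against matched lists. Co-stimulatory genes had a median log2 ratio of -0.11 in NCR+ and 0.12 in CCR6+ ILC3-like cells, a difference of -0.23, although the NCR+ value lies above the -0.13 of all genes measured there. Immediate early genes had -0.16 in NCR+ (percentile 8.88) and 0.10 in CCR6+ cells (percentile 99.9), a difference of -0.26. The list was not measured within clusters, and for its member Fos the NCR+ value depends on their mix. Cluster 6, poor in Fos (47.0 CPM unstimulated, against 971 in cluster 0), held 1074 of the unstimulated and 1382 of the stimulated cells. Fos was 1.05-fold, 1.09-fold and 1.85-fold higher within the 3 NCR+ clusters but at 356 and 349 CPM in all NCR+ cells. The share of such a cluster itself depends on the clustering, at 9.86% and 9.68% with barcodes of at least 200 genes kept. Effector cytokines had 0.078 in ILC3-like and -0.44 in T-like cells, a difference of 0.52, and immediate early genes 0.042 and -0.17, a difference of 0.21. The effector contrast did not hold in alpha beta T-like cells (0.26, -0.30 to 0.59, against -0.15 in gamma delta T-like cells), and counting every cytokine with a UMI gave 0.00066 in T-like cells. The immediate early median was -0.27 in gamma delta and -0.059 (-0.17 to 0.088) in alpha beta T-like cells.

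Ctla4 was 12.3-fold higher in stimulated NCR+ ILC3-like cells. Admixed alpha beta T cells or doublets with them would bring their CD3 chains and Trac, which stood at 0.655% of the alpha beta T-like level (8.85 against 1350.4 CPM) where the Ctla4 difference needed 27.1%. Free Ctla4 RNA would reach both subsets alike, but the stimulated NCR+ level was 24.5 times that of CCR6+ cells. Another mix of the NCR+ clusters would leave single clusters level, but the smallest ratio within a cluster was 7.83-fold. A response of NCR+ cells to IL-23 may remain as a hypothesis, and with 1 library per group any other difference between the libraries stays open.

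Il22 was 7.50-fold higher in stimulated T-like cells, at 42.7% of its level in stimulated ILC3-like cells. RNA of ILC3s carried over by droplets or doublets would bring all abundant ILC3 transcripts to at least that level, but the 20 lowest of 783 genes of at least 200 CPM stood at a median of 20.6% (bootstrap interval 14.2 to 24.6, range 7.44 to 30.5). That interval, added after the value was seen, ends below 42.7% but above the bound set beforehand, 1/2 of that. The 20 genes were picked as the lowest in these same data, so the interval is no error of a carry-over level. RNA carried over at the average ILC3-like mix may account for part of the Il22 and not for all of it. ILC3s clustered among T-like cells, or in doublets with them, would bring the same transcripts only if they had that mix. Among the 20, Upp1 was a leading gene of cluster 6, Cryaa and Cebpd of cluster 3 and Rasl11a of cluster 8. ILC3s of other clusters could bring Il22 with less of these, so such cells stay open as a part or the whole of the cause. The test planned for clustered ILC3s decides nothing. Il22 was at 11286 CPM in the 472 of 483 stimulated T-like cells with a CD3 chain UMI, but the other 11, at the 176 Il22 UMIs of a mean ILC3-like cell, hold too few of the 44290 to alter that level. Incubation and other differences between the libraries stay open beside a response of T cells.

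More stimulated barcodes had under 500 genes, 994 (9.52%) against 241 (2.17%). Damaged cells that kept mitochondrial RNA would show a raised mitochondrial share, but the median of the 959 stimulated barcodes with at least 300 but under 500 genes was 2.49%, against 3.19% in kept cells (9.18% in the 206 unstimulated such barcodes). Free RNA would bring transcripts of epithelial cells, which the sort removes. The summed epithelial markers were 7.46 times higher in those barcodes than in kept cells (96.8 CPM, 72.3 to 127, against 13.0). That sum is 52 UMIs over the 959 barcodes, so free RNA may be present but the number of such droplets cannot be told. Those barcodes also differed from kept cells in Snhg9 (1543 against 40.7 CPM), in Il22 (34544 against 25656 CPM) and in ribosomal protein UMIs (12.4% against 20.2%). Their unstimulated counterparts also held more epithelial RNA (174 against 10.8 CPM), so the higher number in the stimulated library stays unexplained. Median UMIs were 694 in the unstimulated and 529 in the stimulated such barcodes. No deposited barcode of either library held under 500 UMIs, so any below that cannot be counted. With at least 200 genes kept, an unnamed cluster led by Snhg9 held 269 unstimulated and 1024 stimulated barcodes, at medians of 1084 and 534 UMIs. No biological explanation was tested.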

How the results depend on the processing

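The alternatives that left out high Scrublet scores, used CD3 chains alone, left out cluster 7 or left out single dominant cells were chosen after seeing the data. Of the values for shares, lists and Il23r, 83 stayed within their intervals, 46 moved beyond them and 3 reversed. Of those for named genes, 557 stayed, 143 moved and 0 reversed, and the largest move was 4.09 on the log2 scale, for Penk without its top cell. The cause was not tested except where the setting shows it. ILC3-like shares (92.8% unstimulated, 92.6% stimulated) were 90.0% and 83.1% with at least 200 genes, 91.6% stimulated with at most 20% mitochondrial UMIs, 91.0% and 90.8% with Scrublet calls kept in, 93.4% and 93.2% at resolution 0.5, 92.3% and 91.3% with genes scaled over both libraries, 28.3% and 28.8% by own transcripts, 93.6% and 93.3% without the top 8% of Scrublet scores, and 81.7% in both by CD3 chains. T-like shares (5.73% and 5.22%) were 66.1% and 65.8% by own transcripts, 6.63% and 7.22% by CD3 chains, and 5.27% unstimulated without the top scores. By own transcripts, which place ILC3-like cells with a T cell receptor transcript among T-like cells, ILC3-like medians reversed to -0.068 for effector cytokines and 0.0092 for checkpoint receptors, and T-like medians were -0.054 for effector cytokines and 0.50 for STAT3 targets. By CD3 chains, the ILC3-like checkpoint median was -0.46 and the T-like STAT3 median 0.48. The checkpoint median was -0.45 with Scrublet calls kept in and -0.44 without the top scores. Keeping the calls in added only 1 stimulated cell. Its moves, in this median and in the ILC3-like shares, thus come from clustering and naming anew and not from doublets. They show that such shifts can exceed the counting intervals. TMM factors, which raise all ratios of a class by 1 amount, gave ILC3-like medians of 0.20 (effector), 0.63 (STAT3) and -0.19 (checkpoint) and a T-like STAT3 median of 0.48. The ILC3-like STAT3 median was 0.54 without the 50 most abundant genes, 0.53 with per-cell CPM and 0.47 with 10 CPM added, which also gave a checkpoint median of -0.21 by its pull toward 0. Counting members with at least 1 UMI, which adds low genes, gave ILC3-like medians of 0.24 (effector) and -0.12 (checkpoint), a T-like effector median reversed to 0.00066 and a T-like STAT3 median of 0.35. Keeping members of at least 50 CPM, which drops genes, gave ILC3-like medians of 1.21 (effector), 0.48 (STAT3) and -0.52 (checkpoint) and a T-like STAT3 median of 0.35. Thinned cells gave a T-like effector median of -0.62. Beside Penk and Ccl5, other named genes moved by over 1.5-fold. With 10 CPM added, log2 ratios were 2.94 for Ctla4 (3.61) and 2.08 for Prdm1 (2.75) in ILC3-like cells and 2.68 for Elovl6 (3.78) and 2.07 for Swap70 (2.66) in T-like cells. By own transcripts, T-like ratios were 2.64 for Elovl6, 4.16 for Batf (3.47), 2.34 for Sbno2 (3.04), 1.33 for Arid5b (1.98), -0.75 for Cd83 (-1.40) and -0.42 for Hspa1a (-1.31), and by CD3 chains -0.36 for Hspa1a. Without thinning, the share with an Il23r UMI was 43.9% and 61.2% in ILC3-like cells (33.2% and 42.5% thinned) and 52.4% and 71.6% in T-like cells (34.7% and 47.3%), since deeper cells show more genes. No paired analysis was possible because each group is 1 library and the labels give no replicate numbers.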

Other observations

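No test of a hypothesis is reported in this part, and its genes were picked from the marker and gene lists after their values were seen.

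Single marker genes differed between T-like and ILC3-like cells in both directions. The neuropeptide gene Calca was at 159 and 118 CPM (unstimulated and stimulated) in T-like cells, against 16.6 and 15.2 in ILC3-like cells, and the transcription factor gene Hlf at 100.1 and 54.5, against 15.2 and 10.9. Klrb1b, an inhibitory receptor gene of NK cells, was at 118 and 172 CPM in T-like and at 505.5 and 523 in ILC3-like cells. The interleukin 2 receptor chain gene Il2ra was at 259 and 320.5 CPM in T-like and at 416 and 609.5 in ILC3-like cells.

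Single cytokine and signalling genes of NCR+ ILC3-like cells went both ways. Ifng, the interferon of type 1 immunity, was at 5.09 and 31.3 CPM and Gzmb at 50.7 and 83.9, but 9 of 11 cytotoxic effector genes lay within 1.5-fold, and the lineage factor gene Tbx21 was at 22.7 and 20.6 CPM. Csf2, which encodes the growth factor GM-CSF, was lower, at 41.9 and 24.0 CPM, and Tnfsf11 was at 117 and 58.8. Socs3 was at 98.7 and 728 CPM in NCR+ and at 375 and 842 in CCR6+ cells, and Il1r1 at 48.7 and 399 and at 104 and 313.

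RNA of cells that the sort should leave out differed between the libraries. The hemoglobin gene Hbb-bs was at 21.1 CPM in unstimulated and 0.319 CPM in stimulated ILC3-like cells. Summed epithelial markers in kept cells were at 10.8 CPM (9.94 to 11.6) and 13.0 CPM (12.1 to 13.9).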
